A study of Mus musculus with 14 samples.

How the data were processed

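Total RNA was taken from frozen subcutaneous white adipose tissue of male C57BL/6 mice with a column kit and turned into biotinylated cRNA for Affymetrix arrays, per the labels' protocols. The deposited values are microarray intensity on a linear scale, 1 value for each of 45101 probe sets on each of 14 arrays, and were made with MAS5, per the submitters' processing notes. The version and settings of that program are not given in the sources used here. In the values themselves the trimmed mean, leaving out 2% at each end, was 1500 on every array, so the arrays share 1 scale. Signals ran from 0.1 to 112160, and array medians from 531.3 to 617.4. Scaling all arrays to the same mean removes any difference in total RNA per cell. Signals of arrays with 3' probe sets depend on RNA integrity and saturate for abundant transcripts, and the number of arrays, 7 in each group, limits precision.

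Samples were put in the exercised or the sedentary group by the group label of each sample, with replicate numbers from the titles. The labels give 11 days for both groups and an age of 12 weeks. They do not give scan dates, batches, collection hours or whether arrays came from separate mice. No other column of sample values was left unused.

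The test, the filter, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Values were transformed as log2(signal + 46.7), where 46.7 is the 10th percentile of all values, so that log2 differences and folds are on that scale and understate changes of weakly expressed genes. Probe sets with a mean signal under 389.8, the 40th percentile of means, were left out, as were 64 control probe sets. Gene symbols came from the platform annotation, where 34945 probe sets had 1 symbol, 932 had several and 9160 had none in the table used; those with several or none entered no gene-level test. Symbols were updated through Entrez identifiers with a table of genes of the mouse assembly GRCm38.p6, which matched 34741 of those with 1 symbol, while 204 kept the annotation's name. No coordinates were used. After the filter 27022 probe sets remained, and each of 12944 genes was represented by its probe set with the highest mean. Of the 4375 remaining probe sets without a single name, 94 changed (62 higher, 32 lower) when all probe sets were tested. For genes named by the rule, 103 of 104 other probe sets had the same sign, with Tfam the exception. Of the 75 that belong to named genes past the threshold, 47 passed too, 28 did not and 16 had differences over 1.5 times smaller.

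Exercised and sedentary arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 35 lists covered thermogenesis, mitochondria, lipid and glucose metabolism, insulin signalling, adipokines, adipocytes, matrix, vessels, stress, cell cycle, clock, immune responses and markers of other cell types. Each was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, with fry, which tests whether a list's genes move 1 way on balance, and with an exact two-sided permutation test of the list mean over all 3432 assignments of arrays to groups, whose smallest p is 0.000583. All were adjusted over the 35 lists. Some genes are members of several lists. List counts were also adjusted over the list alone.

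The genes named by rule were the 10 with the largest increase and the 10 with the largest decrease among those past the threshold, up to 4 changed members of each list (or the 2 with the smallest p where none changed), and a fixed panel of 13 genes of fat and thermogenesis. The rule named 106 genes.

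Code was tested on simulated data with the levels and spread of these arrays, in which 200 of 12944 genes were changed. Each gene was drawn independently there, so the rates for single genes leave out correlation between genes. Of the changed genes 54% were called at a log2 change of 0.5 and 86% at 1, all with the right sign, and 7.9% of calls were false. Only respiratory complex I was simulated as a list with correlated genes, with no group difference. Its genes shared an array-to-array factor, set larger than the spread of the list mean on these arrays. Camera with the preset correlation called it in 69% of 100 simulations, and with an estimated correlation in 9%. The exact permutation test called it in 9%. Statements on lists therefore do not rest on camera with the preset correlation. They use member counts, which were not simulated for such a list, and the permutation test. Camera with an estimated correlation, which gave false calls as often as the permutation test, is mostly printed beside them.

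Alternatives were quantile normalisation, centring on array medians, other pseudocounts and filters, the mean of all probe sets of a gene, all probe sets, no variance trend, array weights, the replicate number as a block, the Gapdh 3'/5' ratio, lymphocyte or muscle markers as covariates, and each array left out in turn. Added after the data were seen were the permutation test of list means without sedentary array 5, both marker lists together as covariates and leaving out sedentary arrays 5 and 7, the least correlated with their group (median correlations 0.902 and 0.907).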

Results

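Messenger RNA levels were measured on 14 microarrays of subcutaneous white adipose tissue from male C57BL/6 mice, an inbred laboratory strain, aged 12 weeks. In 7 samples the mice had lived for 11 days in cages with a running wheel (exercised), and in 7 the mice had no wheel (sedentary). Each array gave 1 signal for each of 45101 probe sets, and 12944 genes passed the filter on low signal and were tested. Array medians lay between 531.3 and 617.4 signal units. The number of arrays limits the precision of every value. No label says whether each array came from a separate mouse, so the p-values measure the spread between these samples, which may be technical.

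The comparison of exercised with sedentary tissue asked how gene expression in this fat depot changed with voluntary running, in a study whose title concerns exercise and glucose control. Among genes past the threshold, the largest increases were in genes of brown and beige fat. Ucp1, the uncoupling protein that lets mitochondria release heat, had a signal of 2380 ± 3406 (SD, n = 7) in sedentary and 34910 ± 13890 (n = 7) in exercised tissue, and rose by 4.67 on the log2 scale (SE 0.69, adjusted p = 0.00229). Of the genes tested, 29 of 33 in respiratory complex I, 18 of 20 in the tricarboxylic acid cycle and 16 of 21 in fatty acid oxidation rose, although camera did not call these lists once their correlation was estimated (adjusted p = 0.085 with an estimated correlation). Skeletal muscle markers had a median difference of 2.79 (exact permutation adjusted p = 0.0971). The clock genes Arntl and Npas2 fell, while Dbp and Nr1d2, which their proteins activate, rose.

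In all, limma called 716 genes at an adjusted p under 0.05, of which 518 were higher and 198 lower in exercised tissue. Changes over 2-fold were seen in 52 higher and 9 lower genes. At an unadjusted p under 0.05 there were 2825 genes, where chance gives 647. In 347 of the 12944 genes tested the 7 exercised values did not overlap the 7 sedentary ones, which happens by chance in 0.0583% of genes. The median difference over all genes tested was -0.03.

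Besides Ucp1, the largest increases among genes past the threshold were in Fabp3, a fatty acid binding protein (4.08, SE 0.48, adjusted p = 0.000744, with another probe set at 0.30, adjusted p = 0.422), Cox7a1, a cytochrome c oxidase subunit of heart, muscle and brown fat (3.05, SE 0.50, adjusted p = 0.00328), and Slc27a2, a fatty acid transporter (2.88, SE 0.53, adjusted p = 0.00651). Dbp, a transcription factor of the circadian output, rose by 2.76 (SE 0.28). Elovl3, which elongates fatty acids in brown fat, rose by 2.33 (SE 0.34). Smaller increases were measured for Cox8b (2.06, SE 0.52, past the threshold in 21 of 29 alternatives), Aspg (2.04, SE 0.30), Pdk4, which inhibits pyruvate dehydrogenase (1.99, SE 0.28), and Pank1, which catalyses the first step of coenzyme A synthesis (1.91, SE 0.25). All 10 of these genes were above the sedentary median on each of the 7 exercised arrays. The largest decrease among genes past the threshold was in Npas2, a clock factor that binds Arntl (-1.87, SE 0.28, adjusted p = 0.00228). It was followed by Nfil3, a repressor in the clock (-1.41, SE 0.32), and the cytokine Tnf (-1.36, SE 0.35, adjusted p = 0.0358, past the threshold in 14 of 26 alternatives, 0.0079 to 0.0855). Rrad (-1.29), Arntl (-1.28), Cpne6 (-1.25), Emp1 (-1.24), Pdk3, another pyruvate dehydrogenase kinase (-1.07), Cdkn1a, an inhibitor of the cell cycle (-1.01), and Spon2 (-0.94, with another probe set at -0.16, adjusted p = 0.529) completed the list.

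**Figure D1:**
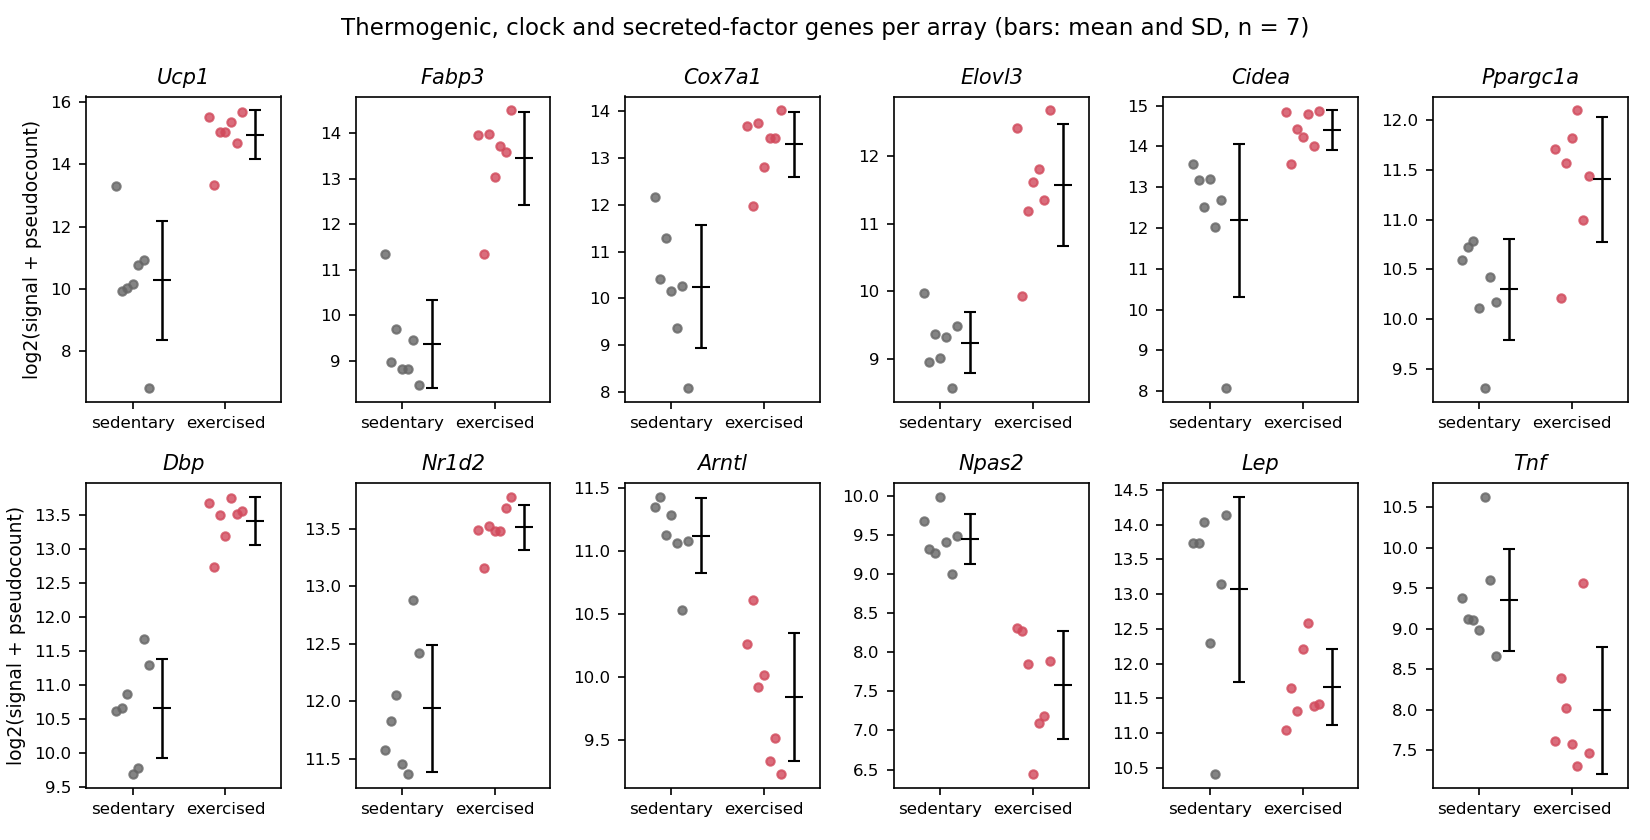
Points give log2(signal + pseudocount) of 12 genes on each of the 7 sedentary (grey) and 7 exercised (red) arrays, and black bars give mean and SD; each panel has its own vertical axis, which does not start at 0. Every exercised Ucp1 value lay above every sedentary one, while the ranges of Ppargc1a overlapped.

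Of 22 thermogenic genes of brown and beige adipocytes tested, 13 rose and 0 fell by limma, and 17 rose when adjusted over the list alone, against 18 higher and 0 lower at an unadjusted p under 0.05. The list had a median difference of 1.43, and its mean was higher by the exact permutation test (adjusted p = 0.00185), and camera called it with the preset correlation (adjusted p = 2.04e-16) but not with an estimated one (adjusted p = 0.085 with an estimated correlation). Fabp3, Ucp1, Cox7a1 and Slc27a2 moved most. Ppargc1a, the coactivator that drives mitochondrial biogenesis, rose by 1.10 (SE 0.28, adjusted p = 0.0307, past the threshold in 19 of 29 alternatives, 0.00479 to 0.12). Cidea, a lipid droplet protein typical of brown fat, differed by 2.21 (SE 0.65, adjusted p = 0.0614), with a signal of 6793 ± 3926 (n = 7) against 22470 ± 6977 (n = 7). Its value was low on sedentary array 7, and without sedentary arrays 5 and 7 the difference was 1.36 (SE 0.24, adjusted p = 0.00618, range over the alternatives 0.00554 to 0.253). Prdm16, a regulator of brown fat identity, differed by 0.39 (SE 0.17, adjusted p = 0.207). Dio2, which activates thyroid hormone, had a signal of 1158 in both groups, but another of its probe sets differed by 1.59 (SE 0.27, adjusted p = 0.00523).

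Most subunits of the respiratory chain that were tested rose. In complex I, 29 of 33 genes rose, and 32 did adjusted over the list alone, among them Ndufs1 (0.78, SE 0.11) and Ndufv2 (0.67, SE 0.07). All 14 genes of complexes II and III rose, also adjusted over the list alone, among them Uqcrfs1 (0.95, SE 0.14) and Cycs (0.66, SE 0.11). In cytochrome c oxidase 9 of 15 rose (13 adjusted over the list alone), and in ATP synthase 10 of 16 rose and 1 fell (13 and 1 adjusted over the list alone). The gene that fell was Atpif1, which encodes the inhibitor of that enzyme (-0.41, SE 0.10, adjusted p = 0.0244). In the tricarboxylic acid cycle and pyruvate dehydrogenase 18 of 20 genes rose (19 adjusted over the list alone), among them Dlat (0.99, SE 0.15) and Suclg1 (0.94, SE 0.18). In fatty acid oxidation 16 of 21 rose (19 adjusted over the list alone), led by Ppara, the nuclear receptor that activates this pathway (1.76, SE 0.24), Ehhadh (1.35), the carnitine carrier Slc25a20 (1.25) and Etfdh (1.05). In mitochondrial biogenesis and translation 10 of 24 rose (13 adjusted over the list alone), including Ppargc1b (0.98, SE 0.21) and the nuclear receptor Esrra (0.73, SE 0.11, with another probe set at 0.19, adjusted p = 0.286). Tfam, the factor that maintains mitochondrial DNA, differed by -0.01 (SE 0.08), with another probe set at 0.29 (SE 0.09, adjusted p = 0.0776). The median differences of these 7 lists were 0.51, 0.61, 0.34, 0.33, 0.68, 0.78 and 0.29, in the order given. All 7 list means were higher by the exact permutation test (adjusted p = 0.00185 for each), but none by camera with its correlation estimated: for ATP synthase the adjusted p = 0.0912 with an estimated correlation, and for each of the other 6 the adjusted p = 0.085 with an estimated correlation.

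Markers of skeletal muscle stood higher on most exercised arrays than on most sedentary ones. The mean log2 level of the 23 markers was 12.58 ± 2.54 (n = 7) in exercised and 10.10 ± 1.74 (n = 7) in sedentary samples, an exact permutation p of 0.0583 (adjusted p = 0.0971). All 23 differences were positive, with a median of 2.79. None of the 23 passed over all genes by limma or adjusted over the list alone, while 16 were higher at an unadjusted p under 0.05. Camera with its preset correlation called the list higher (adjusted p = 0.32 with an estimated correlation). Signals of Ckm, muscle creatine kinase, were 31710 ± 27880 in exercised and 5650 ± 10790 in sedentary tissue, and those of Acta1, skeletal muscle actin, 39270 ± 28960 and 10410 ± 15420 (n = 7 each; both genes were picked after their values were seen). Cox7a1, Cox8b and Fabp3 are also expressed in muscle. With the muscle markers as a covariate, 10 thermogenic genes, 11 of complex I, 8 of complexes II and III, 13 of the tricarboxylic acid cycle and 11 of fatty acid oxidation rose. Of cytochrome c oxidase, ATP synthase and mitochondrial biogenesis, 2 each rose. With that covariate Cox8b differed by 1.80 (SE 0.62, adjusted p = 0.183, range over the alternatives 0.00244 to 0.183), while Ucp1 rose by 4.43 (SE 0.83). The exercised arrays 4 and 1, with muscle means of 8.93 and 9.30, had mitochondrial means of 14.10 and 14.34. Sedentary array 3, with a muscle mean of 13.09, had a mitochondrial mean of 13.76.

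**Figure D2:**
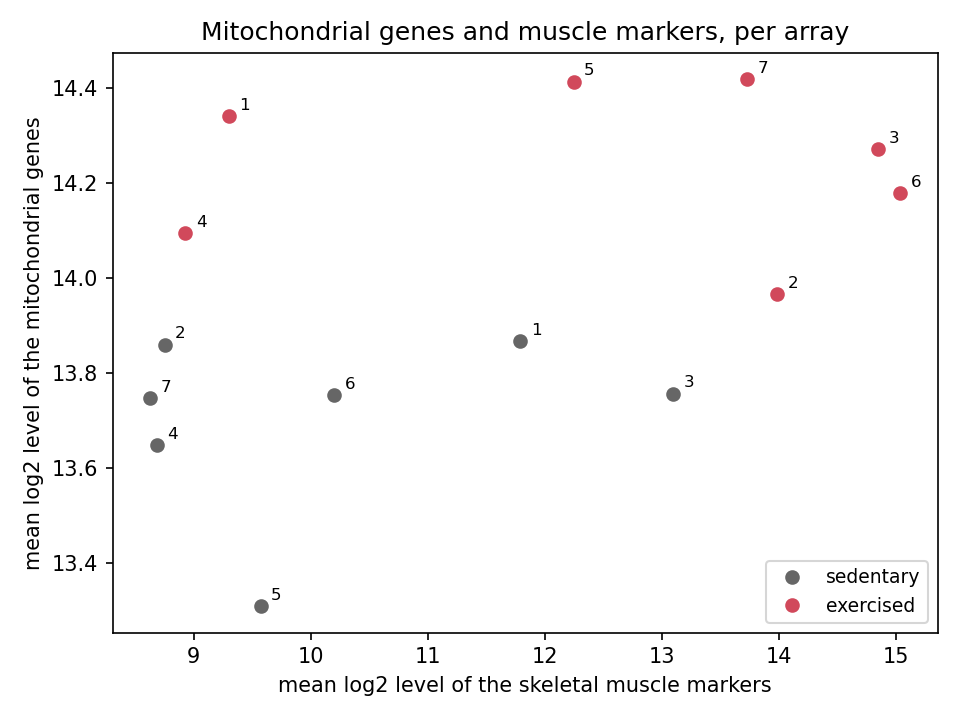
Each point is 1 array, numbered by its replicate, with the mean log2 level of the 23 skeletal muscle markers on the horizontal axis and that of 117 mitochondrial genes on the vertical axis; sedentary arrays are grey and exercised arrays red, and neither axis starts at 0. Exercised arrays lay between 13.97 and 14.42 on the vertical axis and sedentary arrays between 13.31 and 13.87, at low and high muscle levels alike.

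Genes of fatty acid and triglyceride synthesis moved upwards as well, with 9 of 26 that rose and 17 adjusted over the list alone. They included Acacb, the acetyl-CoA carboxylase at the mitochondrial membrane (1.48, SE 0.24, adjusted p = 0.00304), Me1 (0.84, SE 0.22, past the threshold in 13 of 29 alternatives) and Lpin1 (0.80, SE 0.20, past the threshold in 17 of 29 alternatives). Fasn, the fatty acid synthase, differed by 0.56 (SE 0.18, adjusted p = 0.0825). The list mean was higher by the exact permutation test (adjusted p = 0.0051), but the adjusted p = 0.214 with an estimated correlation. In lipolysis and lipid droplets 2 of 17 rose, the droplet coat proteins Plin5 (1.27, SE 0.22) and Plin2 (0.55, SE 0.14, past the threshold in 18 of 29 alternatives), and 5 did adjusted over the list alone (exact permutation adjusted p = 0.00185, and adjusted p = 0.32 with an estimated correlation). In glucose uptake and glycolysis 9 of 19 rose and 16 did adjusted over the list alone, such as Pfkl (1.07, SE 0.22, with other probe sets at 0.65 and 0.18), Ldhb (0.89, SE 0.20) and Slc2a4, the insulin-responsive glucose transporter (0.77, SE 0.21, adjusted p = 0.0467, past the threshold in 11 of 29 alternatives, 0.0128 to 0.33). That list mean was higher by the exact permutation test (adjusted p = 0.00185; adjusted p = 0.085 with an estimated correlation), and 2 of its genes rose with the muscle markers as a covariate. Of the genes of mature adipocytes 3 of 19 rose, Gpd1 (1.002, SE 0.21, with other probe sets at 1.28 and 0.02), Slc2a4 and Pck1 (0.62, SE 0.17, past the threshold in 11 of 29 alternatives), and 7 did adjusted over the list alone (exact permutation adjusted p = 0.00784, and adjusted p = 0.32 with an estimated correlation). Adipoq, which encodes adiponectin, differed by 0.06 (SE 0.08) and Pparg, the master regulator of adipocytes, by 0.19 (SE 0.26). Sedentary array 5 had the lowest means of the 7 sedentary arrays for synthesis, lipolysis and mature adipocyte genes, 12.93, 13.39 and 13.18.

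Among 20 genes of insulin signalling, Irs1, an insulin receptor substrate, rose (0.56, SE 0.14, past the threshold in 19 of 29 alternatives) and Foxo1, a transcription factor that insulin restrains, fell (-0.23, SE 0.06, past the threshold in only 8 of 29 alternatives, adjusted p 0.00732 to 0.203), with the same counts adjusted over the list alone (exact permutation adjusted p = 0.992). Of 20 adipokines and secreted factors, Nrg4 rose (0.90, SE 0.25, adjusted p = 0.0471, past the threshold in 9 of 29 alternatives, 0.00919 to 0.196) and Tnf fell, also adjusted over the list alone. The adipokine list had a median of -0.03 and a mean of -0.20, and the exact permutation test called it lower (adjusted p = 0.0408) where camera did not (adjusted p = 0.777 with an estimated correlation). Lep, which encodes leptin, differed by -1.41 (SE 0.49, adjusted p = 0.105), with signals of 11040 ± 6178 (n = 7) in sedentary and 3411 ± 1454 (n = 7) in exercised tissue. This gene and Tnf (-1.36) lay far below the mean of the adipokine list, which was not tested without them. Without sedentary array 5 the difference of Lep was -1.86 (SE 0.30, adjusted p = 0.00312, range over the alternatives 0.00212 to 0.257). Genes of cholesterol synthesis moved both ways (median -0.07), with 0 of 18 called by limma, 1 higher and 2 lower adjusted over the list alone, and 2 higher and 3 lower at an unadjusted p under 0.05 (exact permutation adjusted p = 0.974). Without sedentary array 5 their mean difference went from -0.01 to -0.08 (SE 0.12), and that of insulin signalling from 0.01 to -0.07 (SE 0.04).

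Genes of the molecular clock moved in opposite directions. Of 17 clock and clock output genes 9 rose and 3 fell, and 11 rose and 5 fell adjusted over the list alone. Dbp had a signal of 1747 ± 875.3 (n = 7) in sedentary and 11150 ± 2398 (n = 7) in exercised samples. Nr1d2, a repressor of Arntl, rose by 1.57 (SE 0.20, adjusted p = 0.00143). Its relative Nr1d1 (1.21, SE 0.28) and the period genes Per3 (1.29), Per2 (0.84) and Per1 (0.57), picked after their values were seen, rose too. Arntl, the core activator, fell by 1.28 (SE 0.20, adjusted p = 0.00304), and another of its probe sets differed by -0.38 (SE 0.16, adjusted p = 0.195). The list mean was higher by the exact permutation test (adjusted p = 0.00185, and adjusted p = 0.085 with an estimated correlation). Its sign depends on how many genes of each direction were listed, here 12 with positive and 5 with negative differences. With the muscle markers as a covariate 5 clock genes rose and 2 fell. The labels do not give the hour at which tissue was collected.

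Immune genes pointed downwards, mostly without single genes passing the test. All 20 interferon response genes had negative differences, with a median of -0.47. By limma 0 of the 20 fell, also adjusted over the list alone, against 10 lower at an unadjusted p under 0.05. The list mean was lower by the exact permutation test (adjusted p = 0.0219), but the adjusted p = 0.33 with an estimated correlation. Without sedentary array 5, whose level was the highest, the mean difference of this list went from -0.49 to -0.31 (SE 0.11, exact permutation adjusted p = 0.0393). All 22 genes of inflammatory cytokines and chemokines were also negative (median -0.51), and only Tnf among them fell, likewise adjusted over the list alone (exact permutation adjusted p = 0.0544; adjusted p = 0.507 with an estimated correlation). All 23 macrophage markers were negative (median -0.34). Of these, Tyrobp, a signalling adaptor of myeloid cells, fell (-0.52, SE 0.15, adjusted p = 0.0482, past the threshold in 9 of 29 alternatives, 0.0231 to 0.313), and 0 fell adjusted over the list alone, against 9 lower at an unadjusted p under 0.05 (exact permutation adjusted p = 0.0456; adjusted p = 0.32 with an estimated correlation). Sedentary array 5 had a mean of 13.05 for the inflammatory genes, where the other 6 sedentary arrays had 10.55 ± 0.22. Without that array the mean difference of the inflammatory genes went from -0.59 to -0.23 (SE 0.11, exact permutation adjusted p = 0.0895), and that of the macrophage markers from -0.35 to -0.25 (SE 0.11, exact permutation adjusted p = 0.0804), which ends the latter's call. Lymphocyte markers, which a lymph node in the depot would bring, had a median of -0.61 and means of 11.82 ± 1.27 (n = 7) and 11.18 ± 1.26 (n = 7) in sedentary and exercised samples. Sedentary array 7 (9.06) and exercised arrays 5 (8.94) and 7 (9.89) lay lowest, so the difference depends on single arrays. None of the 22 passed by limma or adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05 (exact permutation adjusted p = 0.42; adjusted p = 0.756 with an estimated correlation).

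Few genes of stress and growth passed the test. In the oxidative stress response 4 of 23 rose and 5 did adjusted over the list alone, including the mitochondrial enzymes Prdx3 (0.63, SE 0.11) and Sod2 (0.48, SE 0.09), with an exact permutation adjusted p = 0.0421 (0.0804 without sedentary array 5, which ends the call) and an adjusted p = 0.32 with an estimated correlation. In the heat shock and unfolded protein list 2 of 25 rose, the mitochondrial chaperones Hspa9 (0.53, SE 0.08) and Hspd1 (0.31, SE 0.08, past the threshold in 18 of 29 alternatives), while 2 rose and 2 fell adjusted over the list alone and the median was -0.11 (exact permutation adjusted p = 0.282). Of 31 proteasome genes Psmd4 rose (0.24, SE 0.07, past the threshold in 9 of 29 alternatives) and 0 passed adjusted over the list alone, against 7 higher at an unadjusted p under 0.05 (median 0.10, exact permutation adjusted p = 0.0744; adjusted p = 0.488 with an estimated correlation). By limma 0 of 19 apoptosis genes and 0 of 22 cell cycle genes passed, also adjusted over each list alone, against 3 and 7 lower at an unadjusted p under 0.05. Their median differences were -0.14 and -0.39 (exact permutation adjusted p = 0.0558 and 0.218; adjusted p = 0.214 and adjusted p = 0.601 with an estimated correlation). Without sedentary array 5 the mean difference of the cell cycle genes went from -0.41 to -0.21 (SE 0.18), that of the heat shock list from -0.12 to -0.05 (SE 0.06) and that of the immediate early genes from 0.01 to 0.10 (SE 0.11). Of 23 immediate early genes Btg2 fell (-0.44, SE 0.12, past the threshold in 13 of 29 alternatives), and 1 fell adjusted over the list alone; their median was -0.03, their mean 0.01 and the direction of camera downwards (exact permutation adjusted p = 0.974).

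Few markers of vessels, stroma and other tissue passed the test. Of 20 angiogenesis genes Egln3, an oxygen sensor (0.68, SE 0.15), and Vegfa, the vascular growth factor (0.44, SE 0.11, past the threshold in 16 of 29 alternatives, adjusted p 0.0142 to 0.218), rose, and 4 did adjusted over the list alone; the median was -0.04, the mean 0.04 and the direction of camera upwards (exact permutation adjusted p = 0.835). By limma 0 of 28 matrix and collagen genes passed, also adjusted over the list alone, against 5 lower at an unadjusted p under 0.05 (median -0.07, exact permutation adjusted p = 0.443). Likewise 0 of 24 endothelial and 0 of 21 fibroblast and progenitor markers passed, also adjusted over each list alone, with 1 higher and 1 lower, respectively, at an unadjusted p under 0.05 (exact permutation adjusted p = 0.959 and 1). Their medians were 0.04 and 0.00. Of 15 smooth muscle and pericyte markers Abcc9 rose (0.43, SE 0.08), the same adjusted over the list alone, with a median of -0.04 and a mean of 0.14 (exact permutation adjusted p = 0.42). Of 16 epithelial markers Epcam fell (-0.57, SE 0.16, past the threshold in 9 of 29 alternatives), the same adjusted over the list alone, while the median was 0.13 (exact permutation adjusted p = 0.626). By limma 0 of 14 nerve markers passed, also adjusted over the list alone, against 2 higher at an unadjusted p under 0.05, with a median of -0.05 and a mean of 0.07 (exact permutation adjusted p = 0.42). For blood markers 0 of 9 passed, also adjusted over the list alone, against 2 lower at an unadjusted p under 0.05, with a median of -0.08 (exact permutation adjusted p = 0.447). Without sedentary array 5 the mean difference of the angiogenesis genes went from 0.04 to -0.03 (SE 0.08), of the matrix genes from -0.09 to -0.05 (SE 0.09), of the endothelial markers from 0.03 to -0.07 (SE 0.08), of the fibroblast markers from 0.00 to -0.03 (SE 0.13) and of the blood markers from -0.33 to -0.12 (SE 0.29).

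**Figure D3:**
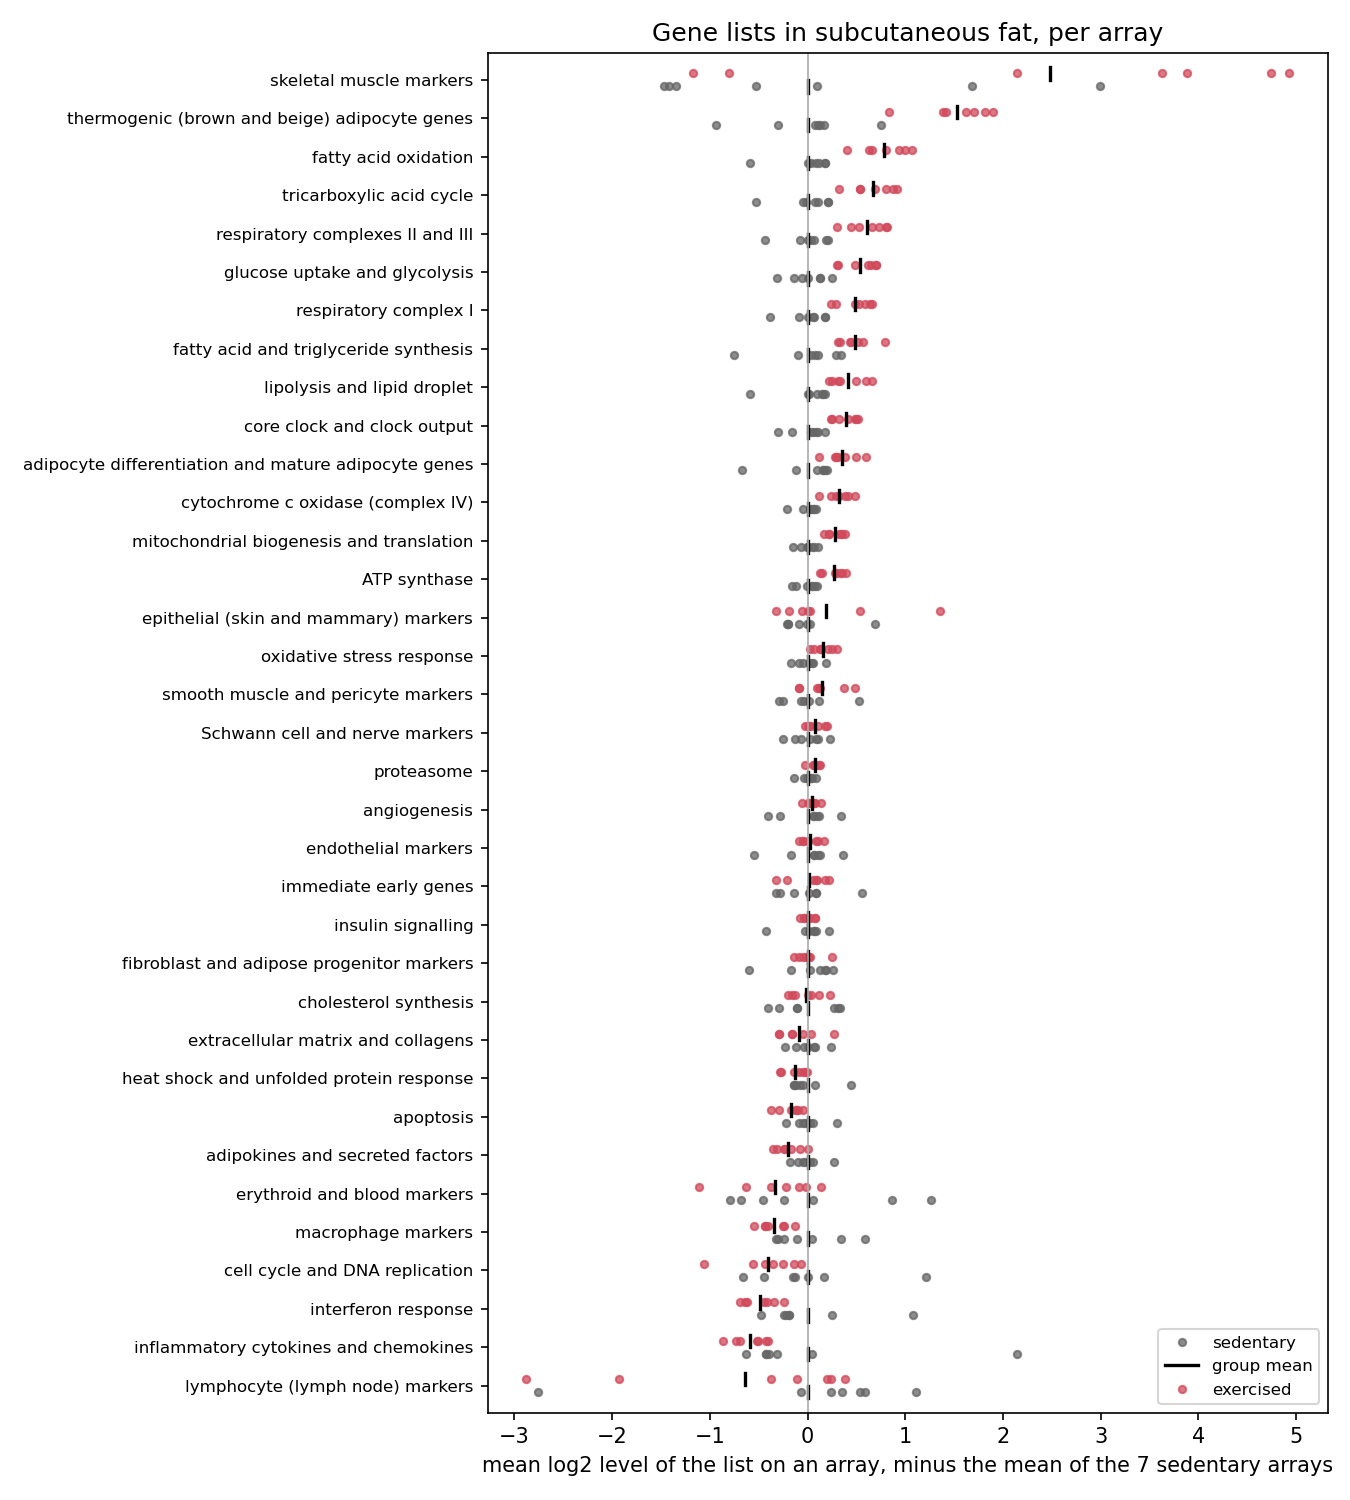
For each of the 35 gene lists, points give the mean log2 level on each sedentary (grey) and exercised (red) array, minus the mean of the 7 sedentary arrays, and black lines give group means. Muscle and lymphocyte markers spread most between arrays, while the means of complexes II and III were 14.66 ± 0.19 (exercised) and 14.05 ± 0.22 (sedentary).

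RNA quality, read from 3' and 5' probe sets of 2 control genes, showed no difference larger than the spread between arrays. For Gapdh the log2 ratio of 3' to 5' signal was -0.45 ± 0.07 (n = 7) in sedentary and -0.40 ± 0.06 (n = 7) in exercised samples (exact permutation p = 0.125, adjusted p = 0.25), and for beta-actin 0.42 ± 0.07 and 0.42 ± 0.11 (exact permutation p = 0.946). Over the 35 lists, camera with its preset correlation called 16 higher and 6 lower, camera with an estimated correlation called 0 (smallest adjusted p = 0.085), fry called 12 and the exact permutation test of list means called 17. The count of 716 genes was 222 with the muscle markers as a covariate, 395 with the Gapdh ratio as a covariate and 398 without exercised array 7. Of the 106 genes named by the fixed rule 76 passed, of which 34 also passed under every alternative that tested them and 42 did not under at least 1. Of the 42, those given above without such a count passed in 25 or more alternatives, except Atpif1 (23 of 29) and Cpne6 (22 of 23). Of the 34, Npas2 was tested under 25 of the 29 alternatives and the others under all.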

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

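The tests of muscle, RNA quality and adipocyte share for the mitochondrial genes, both tests of the clock and all 3 tests of the immune genes were chosen only after the result was seen. Arrays were set apart here when the gap between an extreme value and its nearest neighbour took up an unusually large part (Dixon's 95% limit) of the range of its group. Chance sets apart about 1 in 20 groups, and here 12 of 74 list and quality values and 23 of 212 gene values were.

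The first pattern was the rise of 117 pooled mitochondrial genes by 0.54 (SE 0.10, exact permutation p = 0.000583, the smallest it can give). The tables argue against muscle carried over in the sample as the whole cause, since the difference was 0.52 (SE 0.12) with the muscle markers as a covariate, and against RNA quality, since it was 0.53 (SE 0.11) with the Gapdh 3'/5' ratio as one. A higher share of adipocytes would raise adipocyte genes by as much, and those rose by 0.35 (SE 0.13, exact permutation p = 0.00291). The mitochondrial genes rose by 0.18 more (SE 0.06, exact permutation p = 0.0122), which argues against such a share as the whole cause. It may still account for part, and saturated signals of abundant adipocyte genes would understate their rise. As a hypothesis, mitochondrial transcripts may have risen within fat cells with exercise, although a change in which cells make up the depot, such as more beige adipocytes, was not tested. A difference in collection hour between the groups, which the labels do not give, was not tested for these genes either. A chance split of the arrays is argued against for the counts of genes. Of 100 splits, the real one included, only 1 gave as many changed genes (716, highest other 1). With either direction of a split counted, the same held for as many higher (518, highest other 1) and as many lower (198, highest other 1). The share cannot fall under 1 in 100 here, and splits cannot address chance between mice if arrays share mice. For the counts of lists by camera's preset correlation chance stays open. Set against the 16 lists higher, 19 splits had at least as many in either direction (highest other 21). Set against the 6 lists lower, 89 did (highest other 21).

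The second pattern was the opposite movement within the clock, where 12 output genes differed by 0.995 (SE 0.13) and 5 genes of the Arntl arm by -1.06 (SE 0.15). Those arms were written down after the values were seen and part the list exactly by sign, so their contrast of 2.06 (SE 0.25) restates the pattern and does not decide whether the clock phase differed. Muscle carried over in the sample is argued against as the whole cause, since the contrast was 2.03 (SE 0.31) with the muscle markers as a covariate. A different clock phase stays open, whether from tissue collected at another hour or from a clock shifted by training, because the labels give no hour.

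The third pattern was the lower level of 64 pooled immune genes, with a difference of -0.46 (SE 0.22, exact permutation p = 0.00641). Sedentary array 5, at 13.13 far above the others, is argued against as the whole cause, since the difference without it was -0.26 (SE 0.10, exact permutation p = 0.0105), but the size depended on it. A lower share of all cells other than adipocytes would lower endothelial, fibroblast and smooth muscle markers too, and these did not move down (0.05, SE 0.08), but it was not excluded, since the immune genes differed from them by -0.52 (SE 0.29, exact permutation p = 0.0367), and by -0.25 (SE 0.14, exact permutation p = 0.0659) without sedentary array 5, both within 2 SE. Lymph node carried over in the sample stays open too, since the difference was -0.37 (SE 0.22) with the lymphocyte markers as a covariate, a criterion that was tightened after its value was seen. A biological decrease of immune cells or their activity with exercise could not be separated from these.

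Sedentary array 5 lay below the other 6 sedentary arrays in the mean log2 level of complex IV (gap over range 0.575, at 13.28 against 13.53 ± 0.04), the tricarboxylic acid cycle (0.653), fatty acid oxidation (0.769), fatty acid and triglyceride synthesis (0.603), lipolysis (0.77), insulin signalling (0.625) and adipocyte genes (0.634). It was low likewise for Cycs (0.618), Etfdh (0.619), Hspa9 (0.661), Ldhb (0.599), Lpin1 (0.644), Nrg4 (0.808), Ppara (0.714), Prdx3 (0.653) and Slc2a4 (0.641). It lay above the others for heat shock genes (0.626), inflammatory genes (0.757), Ccnb2 (0.617), Pcna (0.636) and Pdk3 (0.665). Sedentary array 7 was low for lymphocyte markers (0.695, at 9.06 against 12.28 ± 0.40), Cidea (0.718, at 8.08) and Cox8b (0.662, at 9.83), and high for epithelial markers (0.733) and Epcam (0.769). Exercised arrays 5 and 7 were low for lymphocyte markers too, at 8.94 and 9.89. The rule for a single extreme array does not set apart 2 low arrays of 1 group. Sedentary array 6 was low for Arntl (0.59), and sedentary array 1 high for Fabp3 (0.577). Exercised array 2 was low for Aspg (0.571) and Ucp1 (0.584, at 13.33), and exercised array 5 for Ccnb2 (0.683). Exercised array 7 was high for fibroblast markers (0.593) and Ifit3 (0.603), and low for Ighm (0.633) and Rrad (0.696).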

How the results depend on the processing

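The alternatives with both marker lists as covariates and without sedentary arrays 5 and 7 were chosen only after the data were seen. Of 716 called genes 643 were also called after quantile normalisation, 653 after centring on array medians, 707 and 716 with the lower and higher pseudocount, 684 with array weights, 602 with the lymphocyte markers as a covariate and 557 without sedentary arrays 5 and 7. All 716 had the same sign under the alternatives that kept every array and tested them. The exception was the mean of all probe sets of a gene, with 713. With 1 array left out between 714 and 716 were tested and had the same sign. The remainder there includes any called gene that fell under the filter, so it does not count changes of sign. Array weights gave 398 genes lower instead of 198. With the Gapdh ratio as a covariate 395 genes changed (303 higher, 92 lower), with the muscle markers 222 (183 and 39), and with muscle and lymphocyte markers together 194 (145 and 49), and 3 lists were lower. For the 518 higher genes the median difference was 0.56 (median SE 0.12) without covariates, 0.55 (0.13) with the Gapdh ratio and 0.54 (0.14) with the muscle markers. For the 198 lower genes it was -0.43 (0.10), -0.42 (0.12) and -0.41 (0.12). Sizes moved less than their errors, and the errors grew; the cause was otherwise not tested. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry called 1 lower.

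Samples with the same number did not consistently deviate together (correlations -0.098, -0.337, 0.381, 0.293, -0.425, -0.081 and 0.327 for replicates 1 to 7). Only sedentary array 4 matched its own number best. The values gave no clear sign of pairing but cannot exclude it, since muscle and lymphocyte levels also set arrays apart. The labels do not say whether the numbers pair samples. With the replicate number as a block 161 genes changed, 136 higher and 25 lower, and it left 16 lists higher and 6 lower.

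With 1 array left out the count of changed genes ran from 398 to 857, of higher genes from 306 to 593, of lower genes from 79 to 264 and of lists lower from 3 to 7. Single exercised arrays moved the counts by over 1.5 times: without exercised array 1 there were 426 (328 higher, 98 lower), without 3 there were 410 (331, 79), without 5 there were 414 (318, 96) and without 7 there were 398 (306, 92). Lower genes alone moved as much without sedentary array 1 (112), 2 (124) or 3 (97) or exercised array 6 (101), and lists lower without sedentary array 5 (3). Leaving out an array also lowers the power of the test.

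Of 106 named genes, the alternatives other than leaving out 1 array gave 1358 values with the same call, 176 no longer past the threshold, 33 newly past it and 13 of opposite sign; with 1 array left out these were 1278, 171, 17 and 11. For lists they were 520, 45, 6 and 20, and 455, 9, 4 and 22. No named gene or list past the threshold changed sign, and none of opposite sign passed it. The cause was not tested. With the mean of all probe sets of a gene Fabp3 was at 2.192 instead of 4.08, Arntl at -0.831 instead of -1.28, Spon2 at -0.549 instead of -0.94, Pfkl at 0.637 instead of 1.07 and Esrra at 0.459 instead of 0.73, and all 5 still passed. Adipoq was at -0.009 with both marker lists. Dio2 was at -0.066 with array weights, -0.032 with lymphocyte, -0.087 with muscle and -0.135 with both marker lists, -0.063 without sedentary arrays 5 and 7, and from -0.082 to 0.07 with 1 array left out. Its highest value over the 29 alternatives was 0.704, and Dio2 passed the threshold in 1 of them (lowest limma adjusted p = 0.0311). Pparg was at -0.001 with array weights and from -0.032 to 0.299 with 1 array left out. Tfam was at 0.018 after centring, 0.144 with the mean of probe sets, 0.020 with array weights, 0.027 with the Gapdh ratio, 0.053 with lymphocyte and 0.055 with both marker lists, and from -0.049 to 0.031 with 1 array left out.

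For lists the sign is the direction of camera, which can differ from that of the median, and the medians where it turned follow. The list cholesterol synthesis was at 0.077 with the Gapdh ratio and from -0.122 to 0.001 with 1 array left out. Immediate early genes were at -0.027 with the mean of probe sets, 0.10 with array weights, 0.119 with lymphocyte, 0.041 with muscle and 0.193 with both marker lists, 0.128 without sedentary arrays 5 and 7, and from -0.109 to 0.195 with 1 array left out. Epithelial markers were at 0.718 with the filter at the 60th percentile, 0.047 with the Gapdh ratio and from -0.032 to 0.203. Endothelial markers were at 0.014 with array weights, 0.032 with the Gapdh ratio, -0.034 with lymphocyte and -0.030 with both marker lists, -0.014 without sedentary arrays 5 and 7, and from -0.022 to 0.102. Fibroblast markers were at 0.076 with the Gapdh ratio, 0.061 with lymphocyte markers and from -0.15 to 0.072. Smooth muscle markers were at -0.089 with the Gapdh ratio and -0.046 with both marker lists. Blood markers were at 0.127 with array weights, 0.206 without sedentary arrays 5 and 7 and from -0.193 to 0.106. A list was not tested with a covariate made from itself. Signals near the background are least certain: Npas2, Cpne6 and Tnf, at mean signals of 162.2, 207.3 and 250.3 in exercised samples, fell under the filter without sedentary arrays 5 and 7 and without some single sedentary arrays. With the filter at the 60th percentile they, Rrad, Spon2, Pdk3 and Ccnb2 were not tested.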

Other observations

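The tests of genes of coenzyme A and ketone metabolism and of creatine and calcium cycling without Ckmt2 were chosen only after the result was seen, the former since Pank1, Slc5a6 and Acot13 had been noticed among the most changed genes. Of 16 such genes 6 rose, among them Slc5a6, a transporter of the vitamins pantothenate and biotin (1.49), and Coasy, the last enzyme of coenzyme A synthesis (0.93). The mean difference of the list was 0.50 (SE 0.07), to which the 3 genes noticed before it was made contribute. Without these the mean of the other 13 was higher by 0.31 (SE 0.06, unadjusted exact permutation p = 0.000583), and 3 of them rose. The whole list did not pass with an estimated correlation (adjusted p = 0.0571 with an estimated correlation). Of 19 genes of branched-chain amino acid degradation 6 rose, including Bcat2, which starts this pathway (0.87), and Bckdha (0.74). Their mean was higher by 0.45 (SE 0.14, exact permutation adjusted p = 0.00175; adjusted p = 0.138 with an estimated correlation). Of 23 peroxisome genes 5 rose, such as the fatty acid transporter Abcd3 (0.78), Pex16 (0.77) and Crat (0.65), and the mean was higher by 0.43 (SE 0.13, exact permutation adjusted p = 0.00233; adjusted p = 0.138 with an estimated correlation).

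Of 36 genes of the mitochondrial ribosome 7 rose, with a mean higher by 0.19 (SE 0.06, exact permutation adjusted p = 0.0122; adjusted p = 0.141 with an estimated correlation). Genes of the cytosolic ribosome went the other way, against the hypothesis that they rose, with 0 of 25 past limma's threshold and a mean of -0.14 (SE 0.07, exact permutation adjusted p = 0.0748; adjusted p = 0.369 with an estimated correlation). Of 12 genes of creatine and calcium cycling, routes of heat production that do not use Ucp1, 0 rose and Gamt fell (-0.71). Their mean was 0.24 (SE 0.14, exact permutation adjusted p = 0.108; adjusted p = 0.696 with an estimated correlation), but it rested on Ckmt2, the mitochondrial creatine kinase of muscle (3.29, SE 1.28, adjusted p = 0.151). Without that gene the mean of the other 11 was -0.037 (SE 0.043, unadjusted exact permutation p = 0.393), which gives no sign that these 11 rose. Leaving out the highest member after its value was seen lowers the mean by construction. The test therefore does not decide whether the list as a whole rose.

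Some genes outside the fixed rule were picked after their values were seen. Chchd10, a mitochondrial protein, rose by 1.497 (SE 0.17, adjusted p = 0.000629), from a signal of 11920 ± 3506 (n = 7) to 32900 ± 5467 (n = 7). Coq8a, which takes part in coenzyme Q synthesis, rose by 1.04 (SE 0.17), and Gys2, the liver form of glycogen synthase, by 1.40 (SE 0.36). The acute phase and complement genes Lbp (-0.92, SE 0.17), Serpina3n (-0.82, SE 0.20) and Cfb (-0.57, SE 0.14) fell.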
